A study of Mus musculus with 58 samples.

How the data were processed

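Messenger RNA was measured in 58 libraries of mouse liver cells (strain 129SV): 20 of Kupffer cells, 19 of monocyte-derived macrophages and 19 of monocytes. The libraries were made with a 3' tag sequencing kit with unique molecular identifiers, per the labels. The submitters' processing notes name UMI-tools 1.0.1, Trimmomatic 0.39 and 0.39-1, STAR 2.7.5b, RSEM 1.3.1 and DESeq2 (version not given) without their order, and the genome build GRCm38.p6; the step that collapsed identifiers, the gating of the cells and the annotation are not given in the sources used here. The deposited table holds 1 signal per gene and library, normalized counts in which the authors divided gene counts by 1 DESeq2 size factor per library, for 25307 genes. Dividing each column by its smallest step gave whole reads for 100% of the values within 0.01, with size factors from 0.404 to 1.675 and totals from 118687 to 521954 per library. Symbols and positions came from the GENCODE M21 annotation of GRCm38, in which 25272 gene identifiers were matched and 35 were not. Groups and replicate numbers came from the labels, and 9 libraries whose labels join 2 or 3 replicate numbers were used as 1 library each. No 2 libraries held identical values, correlations between replicates were 0.664 to 0.885 across genes, and the reads of every replicate pair differed by more than counting error (chi-square per degree of freedom of at least 2.81).

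The choices in this paragraph were made before the data were examined. Injury groups were compared within each cell type by limma 3.58.1 in R 4.3.3 (trend and robust) on log2(normalized count + 1), with 1 fit per cell type over all 5 groups. Genes with a normalized count of at least 10 in at least 3 libraries were tested: 6159 in Kupffer cells, 6079 in monocyte-derived macrophages and 6112 in monocytes. Cell types were compared by 1 fit over all 58 libraries (7555 genes), and differences between effects were tested as interactions. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 per comparison, two-sided. The 35 gene lists, written down beforehand, were tested with camera (preset correlation 0.01) where at least 5 members were tested, adjusted over the lists, and list members were also adjusted over the list alone. Named genes were taken by a rule: of the genes past the threshold, with a mean of at least 50 in the higher group, no overlap between the libraries of the groups, and no predicted gene, pseudogene or immunoglobulin or T cell receptor segment, the 6 with the largest rise and the 6 with the largest fall; up to 3 members of each list; and a fixed set of marker genes. Gpbar1, 1 of these markers, is not analysed here. Shares of reads from marker lists were computed per library and carry no test.

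Alternatives were a pseudocount of 5, no filter on low values, all libraries scaled to equal totals, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, libraries with single replicate numbers only, each library left out in turn, and camera with an estimated correlation. A covariate for the endothelial level was added after the data were seen. The test was checked on simulated data in which 200 genes were changed 2-fold or 4-fold: for CBDL6w against Sham6w limma recovered 25.3% and 76.3% of those tested in Kupffer cells, 8.5% and 62.8% in monocyte-derived macrophages and 17.4% and 54.7% in monocytes, with 8.7%, 9.5% and 4.2% false calls. For DSS against Sham6w, simulated with nothing changed, limma called 0 genes in each cell type. For the difference in the effect of colitis with ligation it recovered 7.4% and 44.1%, 1.1% and 36.2%, and 12.0% and 36.8%. Small changes were thus often missed, and a gene without a call is not shown to be unchanged. Unique identifiers limit, but do not remove, copies of 1 molecule, so totals bound only counting error.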

Results

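The series measured messenger RNA in 3 cell types isolated from livers of 129SV mice: Kupffer cells (resident liver macrophages), monocyte-derived macrophages and monocytes. The mice fell into 5 injury groups: controls at 6 weeks (Sham6w), bile duct ligation at 2 weeks (CBDL2w, onset of cholestatic injury) and at 6 weeks (CBDL6w, advanced cholestatic injury), acute colitis (DSS), and advanced cholestatic injury with acute colitis as a second hit (CBDL+DSS). There were 58 libraries in 15 groups, 4 in each except 3 each for Sham6w monocyte-derived macrophages and monocytes. The labels of 9 joined 2 or 3 replicate numbers. Recovered read totals ran from 228741 to 521954 in Kupffer cells, 118687 to 461071 in monocyte-derived macrophages and 235531 to 377725 in monocytes. Between 8885 and 13360 genes were detected per library. Levels are mean normalized counts ± SD over libraries, and changes are log2 ± SE from the fit, with n = 4 libraries per group unless said. Apart from the replicate numbers, no label says whether replicates were separate animals, so the p-values measure only the spread between these samples. Every gene named as changed between 2 groups had all libraries of 1 group above all of the other. No label gives a time for DSS or CBDL+DSS, so the time after ligation is not known to match between CBDL+DSS and CBDL6w. Controls are at 6 weeks only, so CBDL2w also differs from them in time. In 27 of 42 comparisons the balance of higher and lower genes turned over in at least 1 alternative or without 1 library, so that balance is a count and not a direction. For marker lists of other cells and of RNA quality, ratios of the mean share of reads are given where all libraries of 1 group lay above all of the other, for lists with at least 0.005% of the reads in 1 group. Gene positions are on GRCm38. Each list call by camera held with an estimated inter-gene correlation except where a second p stands beside it. List members not counted as changed did not pass the test.

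First, the 3 cell types of control livers were compared. Kupffer cells stood above monocytes in Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), a lectin of resident Kupffer cells, at 453 ± 34.7 against 16.8 ± 9.65 normalized counts (log2 difference 4.85 ± 0.71, adjusted p = 5.79e-07). They were also higher in the hemoglobin scavenger receptor Cd163 (5.29 ± 0.63) and in the complement receptor Vsig4 (3.94 ± 0.61). Monocytes stood above Kupffer cells in Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), the surface marker of classical monocytes, at 173 ± 47.3 normalized counts against 0.684 ± 1.00 (adjusted p = 3.67e-15), and in Ccr2 (-3.14 ± 0.25). Against monocyte-derived macrophages, Kupffer cells were higher in the apolipoproteins Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188; log2 difference 2.17 ± 0.25, adjusted p = 7.09e-09) and Apoc1 (3.79 ± 0.65) and in the complement component C1qc (2.26 ± 0.44). They were lower in Spn (-5.0 ± 0.54), a sialoglycoprotein of blood leukocytes, and in the chemokine receptor Ccr2 (-2.01 ± 0.25). Monocyte-derived macrophages were lower than monocytes in Ly6c2 (-4.24 ± 0.54) and higher in the growth factor receptor Csf1r (1.24 ± 0.21).

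Of the genes typical of Kupffer cells, 19 of 21 were higher (20 adjusted over the list alone, camera adjusted p = 8.75e-20) in Kupffer cells than in monocytes. Of the genes typical of classical monocytes, 16 of 17 were lower (16 adjusted over the list alone, camera adjusted p = 3.83e-27). Between Kupffer cells and monocyte-derived macrophages, the genes common to tissue macrophages differed, and 14 of 16 were higher (14 adjusted over the list alone, camera adjusted p = 8.66e-14). Markers of other cells also differed: of endothelial genes, 12 of 15 were lower (14 adjusted over the list alone, camera adjusted p = 1.42e-14) in Kupffer cells than in monocytes, and between monocyte-derived macrophages and monocytes 13 of 15 were lower (14 adjusted over the list alone, camera adjusted p = 3.78e-18). Endothelial markers made up 0.366 to 0.634% of the reads in Sham6w monocytes and 0.0362 to 0.0730% in Sham6w monocyte-derived macrophages. In all, 688 genes were higher and 516 lower in Kupffer cells than in monocyte-derived macrophages, 565 higher and 645 lower than in monocytes, and 147 higher and 318 lower in monocyte-derived macrophages than in monocytes. With edgeR on the recovered reads the first split was 421 and 523 and the third 103 and 138, and the median of all genes moved from 0.144 to 0.025 and from -0.122 to 0. Without MoMF Sham6w replicate 1+2+5 the first total was 676, and the third was 269 without Mo Sham6w replicate 1+2+5 and 289 without replicate 3+6.

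In Kupffer cells, the onset of cholestatic injury was compared with the controls. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the fractalkine receptor, rose from 30.8 ± 27.3 to 259.8 ± 24.6 normalized counts (log2 change 3.36 ± 0.33, adjusted p = 3.24e-06). The matrix protein Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200) rose from 13.0 ± 13.2 to 232 ± 108 (log2 change 4.46 ± 0.62, adjusted p = 8.64e-05), and the tetraspanin Cd63 (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822) rose from 17.3 ± 10.2 to 156 ± 36.5 (log2 change 3.25 ± 0.38, adjusted p = 1.5e-05). Clec4f fell from 453 ± 34.7 to 114 ± 18.3 (log2 change -1.99 ± 0.28, adjusted p = 8.64e-05), with falls also in Cd163 (-2.30 ± 0.35), the complement component C6 (-2.05 ± 0.37) and Vsig4 (-1.43 ± 0.23). Among Kupffer cell genes, 8 of 21 fell (1 rose and 14 fell adjusted over the list alone, camera adjusted p = 8.57e-13). The lipid- and scar-associated macrophage genes moved up, and 5 of 19 rose (12 adjusted over the list alone, camera adjusted p = 3.78e-10). Of the genes of monocyte migration, 4 of 12 rose (5 adjusted over the list alone, camera adjusted p = 2.33e-07), led by the chemokine receptors Ccr1 (2.91 ± 0.46) and Ccr2 (1.89 ± 0.26). Of the matrix remodelling genes, 3 of 10 rose (3 adjusted over the list alone, camera adjusted p = 0.00117), among them the membrane metalloproteinase Mmp14 (2.36 ± 0.40).

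Of the interferon-response genes, 3 of 22 fell (5 adjusted over the list alone, camera adjusted p = 2.75e-06), and of the genes of heme and iron handling 3 of 15 fell (3 adjusted over the list alone, camera adjusted p = 0.000257). Among ribosomal protein genes, 11 of 75 rose (40 adjusted over the list alone, camera adjusted p = 2.68e-24). Of the transcripts of the mitochondrial genome, 9 of 15 fell (14 adjusted over the list alone, camera adjusted p = 2.96e-14). The largest fall was in the major urinary protein gene Mup9 (-5.87 ± 0.79), a product of hepatocytes whose reads are shared with near-identical Mup genes, so its own level is uncertain. Marker shares stood apart by ratios of 0.65 (mitochondrial), 1.42 (ribosomal), 0.25 (hepatocyte) and 0.35 (endothelial). In total 67 genes rose and 100 fell, or 123 and 87 with every library at an equal total. The total of 167 became 92, 85 or 88 without Sham6w replicate 1, 2 or 3, and 105 or 87 without CBDL2w replicate 2 or 3.

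Advanced cholestatic injury was compared with the same control Kupffer cells. Cx3cr1 rose from 30.8 ± 27.3 to 314 ± 77.7 normalized counts (log2 change 3.61 ± 0.33, adjusted p = 4.49e-07), Cd63 from 17.3 ± 10.2 to 194 ± 90.3 (log2 change 3.46 ± 0.38, adjusted p = 9.6e-06) and Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557) from 28.5 ± 8.23 to 128 ± 46.5 (log2 change 2.09 ± 0.26, adjusted p = 2.87e-05). The lipid receptor Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) rose from 3.00 ± 1.83 to 27.1 ± 7.70 (log2 change 2.89 ± 0.51, adjusted p = 0.00149). Clec4f fell from 453 ± 34.7 to 112 ± 66.2 (log2 change -2.22 ± 0.28, adjusted p = 3.45e-05) and Cd163 fell by 3.09 on the log2 scale (from 536 ± 50.8 to 75.6 ± 56.3). The mannose receptor Mrc1 (-0.89 ± 0.14), Vsig4 (-1.66 ± 0.23) and the iron exporter Slc40a1 (-0.83 ± 0.17) also fell. Of the Kupffer cell genes, 1 of 21 rose and 8 fell (1 rose and 15 fell adjusted over the list alone, camera adjusted p = 3.6e-12). Again 5 of 19 lipid- and scar-associated genes rose (7 adjusted over the list alone, camera adjusted p = 2.1e-06). Of the monocyte migration genes, 4 of 12 rose (4 adjusted over the list alone, camera adjusted p = 1.65e-05). Of the heme and iron genes, 3 of 15 fell (6 adjusted over the list alone, camera adjusted p = 0.000452). Also 13 of 75 ribosomal protein genes rose (29 adjusted over the list alone, camera adjusted p = 4.58e-21). Marker shares stood apart by 1.36 (ribosomal) and 0.31 (endothelial). In total 75 genes rose and 125 fell, against 98 and 100 with equal totals and 134 and 145 with DESeq2. Leaving out Sham6w replicate 2, 3 or 4 gave totals of 104, 99 or 102, and leaving out CBDL6w replicate 4 gave 107.

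Onset and advanced injury were then compared directly in Kupffer cells. No gene passed in limma (0 of 6159, with 449 at an unadjusted p under 0.05), against 0 in edgeR and 10 in DESeq2. Cx3cr1 stood at 259.8 ± 24.6 at 2 weeks and 314 ± 77.7 at 6 weeks (log2 change -0.24 ± 0.33, adjusted p = 0.894), and Clec4f at 114 ± 18.3 and 112 ± 66.2 (log2 change 0.23 ± 0.28, adjusted p = 0.877). Without CBDL6w replicate 1 or 2 the count was 1.

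Acute colitis alone was compared with the controls in Kupffer cells. Apoe fell from 2155 ± 438 to 546 ± 150.1 normalized counts (log2 change -1.99 ± 0.17, adjusted p = 2.64e-07), the lectin Cd207 from 83.2 ± 18.8 to 20.1 ± 6.67 (log2 change -2.03 ± 0.23, adjusted p = 1.25e-05) and Clec4f from 453 ± 34.7 to 187 ± 15.9 (log2 change -1.27 ± 0.28, adjusted p = 0.00867). The interferon-induced GTPase Ifi47 rose from 27.1 ± 6.43 to 112 ± 25.3 (log2 change 2.00 ± 0.37, adjusted p = 0.00218). Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245) rose from 20.1 ± 3.30 to 122 ± 45.1 (log2 change 2.48 ± 0.51, adjusted p = 0.00579), and securin, Pttg1, rose from 13.4 ± 18.4 to 62.5 ± 4.38 (log2 change 3.20 ± 0.73, adjusted p = 0.0115). The prostaglandin-degrading enzyme Hpgd (-1.74 ± 0.24), the transcription factor Maf (-1.10 ± 0.15), Mrc1 (-1.25 ± 0.14), Vsig4 (-1.19 ± 0.23), C1qa (-0.69 ± 0.15) and Slc40a1 (-1.09 ± 0.17) fell. Of the genes common to tissue macrophages, 11 of 16 fell (13 adjusted over the list alone, camera adjusted p = 1.22e-10). Among targets of the sterol-sensing LXR receptors, 5 of 12 fell (6 adjusted over the list alone, camera adjusted p = 0.000221), including the phospholipid transfer protein Pltp (-1.41 ± 0.25). Of the heme and iron genes, 4 of 15 fell (7 adjusted over the list alone, camera adjusted p = 0.000704). Of the cell cycle genes, 3 of 11 rose (7 adjusted over the list alone, camera adjusted p = 2.06e-05). Among Kupffer cell genes, 6 of 21 fell (1 rose and 12 fell adjusted over the list alone, camera adjusted p = 4.87e-06 and adjusted p = 0.15 with an estimated correlation). Of the ribosomal protein genes, 32 of 75 rose (52 adjusted over the list alone, camera adjusted p = 3.13e-27). Among mitochondrial transcripts, 13 of 15 fell (14 adjusted over the list alone, camera adjusted p = 1.77e-11 and adjusted p = 0.0683 with an estimated correlation). Hepatocyte markers held 0.315% of the reads of DSS replicate 4 and 0.031 to 0.059% in the other 3 libraries, and shares stood apart by 0.59 (mitochondrial), 1.5 (ribosomal) and 3.63 (neutrophil). In total 206 genes rose and 280 fell, or 335 and 206 with equal totals. The total of 486 was 214, 305 or 316 without Sham6w replicate 2, 3 or 4, and 219 or 321 without DSS replicate 2 or 3.

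The second-hit group was compared with the controls and with advanced injury alone. Against Sham6w, Kupffer cells of CBDL+DSS rose in Cd63 from 17.3 ± 10.2 to 206 ± 28.3 (log2 change 3.66 ± 0.38, adjusted p = 9.48e-07), in the macrophage elastase Mmp12 from 7.09 ± 3.45 to 55.8 ± 33.7 (log2 change 2.65 ± 0.56, adjusted p = 0.00792) and in Cx3cr1 from 30.8 ± 27.3 to 137 ± 4.24 (log2 change 2.44 ± 0.33, adjusted p = 3.97e-05). They fell in Clec4f from 453 ± 34.7 to 153 ± 23.0 (log2 change -1.57 ± 0.28, adjusted p = 0.00142), Maf (-1.11 ± 0.15), Cd163 (-1.67 ± 0.35) and the interferon-induced Ifi44 (-1.43 ± 0.30). Of the lipid- and scar-associated genes, 5 of 19 rose (13 adjusted over the list alone, camera adjusted p = 1.97e-11). Of the interferon-response genes, 2 of 22 fell (9 adjusted over the list alone, camera adjusted p = 7.06e-08 and adjusted p = 0.052 with an estimated correlation). Shares stood apart by 0.69 (mitochondrial), 1.28 (ribosomal), 3.16 (neutrophil) and 0.4 (endothelial). In total 99 genes rose and 105 fell, or 123 and 89 with equal totals. The total of 204 was 134 or 132 without Sham6w replicate 1 or 2, and 132 or 108 without CBDL+DSS replicate 4+5 or 6.

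Against CBDL6w, Kupffer cells rose in Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438) from 123 ± 53.6 to 296 ± 45.1 (log2 change 1.36 ± 0.23, adjusted p = 0.00561), in Mrc1 from 171 ± 15.4 to 318 ± 14.8 (log2 change 0.89 ± 0.14, adjusted p = 0.00274). They also rose in the lipid droplet protein Hilpda (2.05 ± 0.37) and in the interleukin-15 receptor chain Il15ra (3.52 ± 0.61). Ccr2 fell from 128 ± 46.5 to 38.7 ± 5.29 (log2 change -1.63 ± 0.26, adjusted p = 0.00274). Of the inflammatory mediator genes, 2 of 17 rose (7 adjusted over the list alone, camera adjusted p = 3.46e-06 and adjusted p = 0.396 with an estimated correlation). Of the genes induced by tissue dissociation, 5 of 22 rose (17 adjusted over the list alone, camera adjusted p = 4.37e-10 and adjusted p = 0.277 with an estimated correlation). Those dissociation genes held 0.751 to 1.34% of the reads in CBDL+DSS and 0.50 to 0.77% in CBDL6w, and a share stood apart by 2.73 (neutrophil). In total 58 genes rose and 49 fell. The total was 69 or 53 without CBDL6w replicate 1 or 2 and 68, 61, 50 or 28 without CBDL+DSS replicate 1+3, 2, 4+5 or 6. Only 2 of the 4 CBDL+DSS libraries carried a single replicate number, and the total over libraries with single numbers was 20.

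Whether colitis acted differently in ligated and unligated mice was tested as the difference of those effects, (CBDL+DSS minus CBDL6w) minus (DSS minus Sham6w). In Kupffer cells the effect of colitis was more positive with ligation for Vsig4 (log2 difference 2.55 ± 0.33, adjusted p = 0.000109), Mrc1 (log2 difference 2.14 ± 0.19, adjusted p = 6.56e-07), Clec4f (1.92 ± 0.39), Cd207 (2.37 ± 0.32), Apoe (1.93 ± 0.24), the efferocytosis receptor Mertk (1.39 ± 0.24) and the glucocorticoid-induced genes Fkbp5 (3.76 ± 0.59) and Klf9 (2.67 ± 0.40). It was more negative for Pttg1 (log2 difference -4.54 ± 1.03, adjusted p = 0.0126), the chromatin protein Hmgn2 (-2.46 ± 0.46), Ifi47 (-2.38 ± 0.52) and Ccr2 (-1.56 ± 0.36). Among Kupffer cell genes, 10 of 21 passed upward (14 adjusted over the list alone, camera adjusted p = 4.04e-09 and adjusted p = 0.0774 with an estimated correlation), a more positive effect of colitis with ligation. Among the genes common to tissue macrophages, 6 of 16 passed upward (11 passed upward and 1 passed downward adjusted over the list alone, camera adjusted p = 4.14e-06). Among LXR targets, 6 of 12 passed upward (6 adjusted over the list alone, camera adjusted p = 2.85e-05). Among cell cycle genes 4 of 11 passed downward (4 adjusted over the list alone, camera adjusted p = 4.15e-05), and among ribosomal protein genes 25 of 75 passed downward (43 adjusted over the list alone, camera adjusted p = 1.52e-25). In total 231 genes passed upward and 140 downward. The median of all genes was 0.137 here and 0.035 with edgeR. The total of 371 was 191 without Sham6w replicate 2, 227 without DSS replicate 2, and 239 or 244 without CBDL+DSS replicate 2 or 6.

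**Figure D1:**
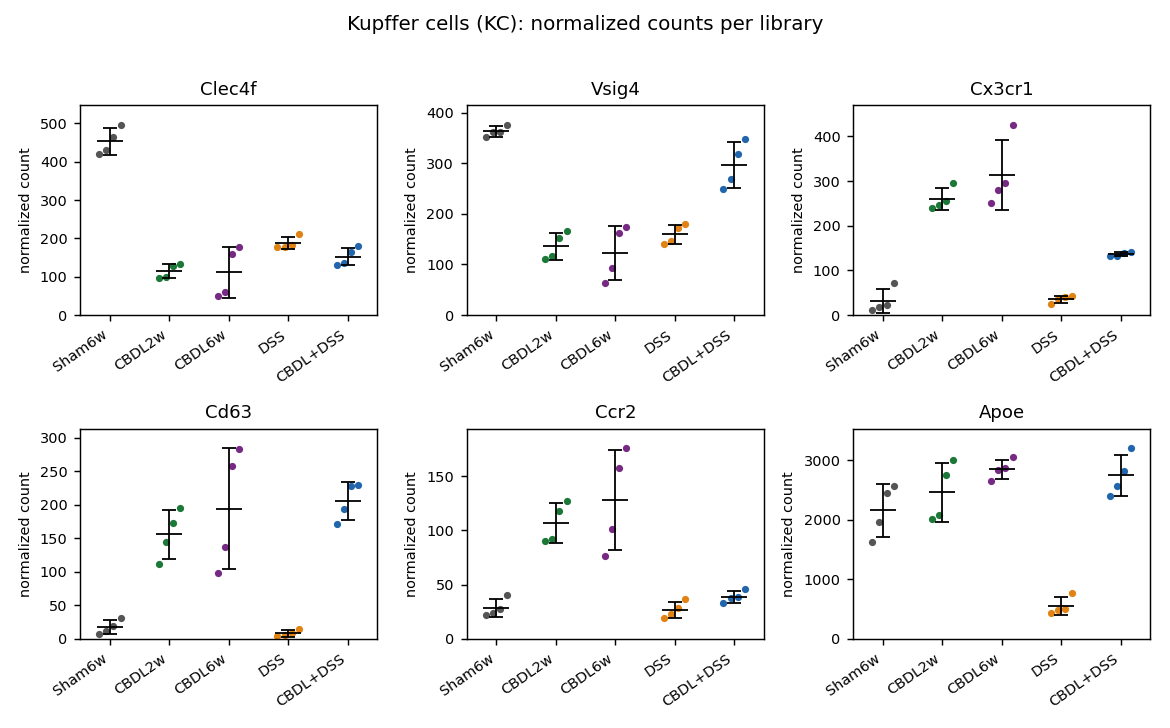
Normalized counts of Clec4f, Vsig4, Cx3cr1, Cd63, Ccr2 and Apoe in each Kupffer cell library (points), by injury group, with the mean and SD of the 4 libraries. Clec4f averages 453.3 in Sham6w and 111.8 in CBDL6w, and Cx3cr1 averages 30.8 and 313.7.

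In monocyte-derived macrophages onset was compared with 3 control libraries. Osteopontin, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 1.31 ± 2.27 to 137 ± 55.5 normalized counts (log2 change 6.25 ± 0.50, adjusted p = 9.19e-08). Trem2 rose from 0.362 ± 0.627 to 20.7 ± 7.65 (adjusted p = 2.65e-05), the glycoprotein Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929) from 0.327 ± 0.567 to 8.64 ± 1.65 (adjusted p = 0.0134) and Fn1 from 53.5 ± 25.2 to 654 ± 106 (log2 change 3.70 ± 0.38, adjusted p = 3.92e-06). Rises were also found in the angiogenic factor Vegfa (3.67 ± 0.68), the chemokine Cxcl2 (2.64 ± 0.26), the endotoxin co-receptor Cd14 (2.18 ± 0.36), Ccr2 (1.56 ± 0.27) and the MHC class II chaperone Cd74 (0.96 ± 0.21). Clec4f (-3.06 ± 0.61), Spn (-2.02 ± 0.39), the chemokine Ccl5 (-3.48 ± 0.68) and the mitotic gene Top2a (-2.91 ± 0.58) fell. Of the classical monocyte genes, 5 of 14 rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000125 and adjusted p = 0.0864 with an estimated correlation). Of the patrolling monocyte genes, 4 of 14 fell (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.000227 and adjusted p = 0.0788 with an estimated correlation). Of the lipid- and scar-associated genes, 4 of 20 rose (6 adjusted over the list alone, camera adjusted p = 1.67e-05 and adjusted p = 0.0726 with an estimated correlation). Among Kupffer cell genes, 5 of 20 fell (15 adjusted over the list alone, camera adjusted p = 9.59e-13 and adjusted p = 0.0847 with an estimated correlation). Kupffer cell RNA in controls (Clec4f 78.4, injury groups 8.45 to 22.3) was not tested as a source. The immunoglobulin gene Igkc fell (-4.55 ± 0.60), and marker shares stood apart by 0.74 (mitochondrial), 1.31 (ribosomal), 0.26 (hepatocyte), 0.06 (B and plasma cell), 0.18 (T and NK cell), 0.25 (endothelial) and 0.49 (dendritic). In total 103 genes rose and 83 fell, or 70 and 95 with edgeR. The total of 186 became 440 without Sham6w replicate 3, and 114 or 118 without CBDL2w replicate 1 or 3.

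At the advanced stage Spp1 rose from 1.31 ± 2.27 to 27.9 ± 6.01 (log2 change 4.06 ± 0.50, adjusted p = 0.000246), Ccr2 from 127 ± 72.8 to 359.5 ± 83 (log2 change 1.61 ± 0.27, adjusted p = 0.00263), Plac8 from 61.0 ± 25.0 to 186 ± 54.0 (log2 change 1.65 ± 0.29, adjusted p = 0.00328) and the secreted matrix protein Tgfbi from 76.8 ± 34.6 to 224 ± 31.3 (log2 change 1.61 ± 0.26, adjusted p = 0.00241). The heat shock protein Hsp90aa1 (-1.26 ± 0.23), the matrix protein Sparc (-3.91 ± 0.53), the immunoglobulin joining chain Jchain (-4.25 ± 0.82) and the endothelial phosphatase Ptprb (-2.46 ± 0.48) fell. Of the classical monocyte genes, 3 of 14 rose (6 adjusted over the list alone, camera adjusted p = 3.21e-05 and adjusted p = 0.157 with an estimated correlation). Marker shares stood apart by 0.68 (dissociation), 0.33 (hepatocyte), 0.07 (B and plasma cell), 0.2 (endothelial) and 0.3 (erythroid and platelet). In total 25 genes rose and 49 fell. The total of 74 was 205 (149 up, 56 down) or 120 (74 up, 46 down) without Sham6w replicate 3 or 4+6, which turned the balance over, and 49 without CBDL6w replicate 1. Libraries with single numbers, which left 1 control, gave 17 genes (13 up, 4 down).

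Between onset and advanced injury, Cxcl2 was higher at 2 weeks, at 575 ± 128 against 119 ± 6.94 normalized counts (log2 change 2.24 ± 0.24, adjusted p = 2.5e-05). Apoe was also higher (1.23 ± 0.20), a call lost without CBDL2w replicate 1 or 3. Of the matrix remodelling genes, 1 of 12 rose (5 adjusted over the list alone, camera adjusted p = 5.32e-09). Among the inflammatory mediator genes, 1 of 19 rose (6 adjusted over the list alone, camera adjusted p = 1.68e-10 and adjusted p = 0.0649 with an estimated correlation). Marker shares stood apart by 0.39 (T and NK cell) and 2.47 (erythroid and platelet). In limma 5 genes were higher and 0 lower (391 at an unadjusted p under 0.05, 26 higher and 5 lower with DESeq2). Without 1 library the count of 5 was 1, 2, 1 or 2 for CBDL2w replicates 1 to 4, and 10, 3 or 3 for CBDL6w replicates 2, 3 and 4.

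Colitis alone raised Plac8 from 61.0 ± 25.0 to 267 ± 57 (log2 change 2.19 ± 0.29, adjusted p = 0.000421) and the guanylate-binding protein Gbp2 from 1.34 ± 1.49 to 28.8 ± 14.5 (log2 change 3.68 ± 0.73, adjusted p = 0.0146) in monocyte-derived macrophages. Fn1 fell from 53.5 ± 25.2 to 13.0 ± 6.72 (log2 change -2.01 ± 0.38, adjusted p = 0.011) and Apoe from 488 ± 151 to 178 ± 22.3 (log2 change -1.41 ± 0.21, adjusted p = 0.00132). Kupffer cell RNA in controls was again not tested. Of the interferon-response genes, 3 of 21 rose (4 adjusted over the list alone, camera adjusted p = 8.86e-05 and adjusted p = 0.262 with an estimated correlation). Of the mitochondrial transcripts, 6 of 14 fell (12 adjusted over the list alone, camera adjusted p = 1.27e-12 and adjusted p = 0.205 with an estimated correlation). Shares stood apart by 0.51 (mitochondrial), 0.42 (hepatocyte), 0.21 (B and plasma cell) and 4.85 (endothelial). In total 77 genes rose and 49 fell, or 101 and 104 with DESeq2. The total of 126 was 289 without Sham6w replicate 3, and 55, 37 or 53 without DSS replicate 2, 3 or 5+6.

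The second-hit group showed the most genes changed against controls in this cell type, 280 up and 316 down. Spp1 rose from 1.31 ± 2.27 to 103 ± 20.9 (log2 change 5.91 ± 0.50, adjusted p = 2.73e-07), Trem2 from 0.362 ± 0.627 to 53.1 ± 3.89 (adjusted p = 2.98e-07), Gpnmb from 0.327 ± 0.567 to 52.9 ± 30.4 (adjusted p = 2.84e-05), Cd63 from 32.5 ± 26.3 to 357 ± 27.5 (log2 change 3.69 ± 0.54, adjusted p = 0.00014) and Apoe from 488 ± 151 to 2449 ± 598 (log2 change 2.35 ± 0.21, adjusted p = 3.35e-07). The complement component C1qb (1.64 ± 0.35), the cholesterol exporter Abca1 (2.49 ± 0.50), Cd74 (1.16 ± 0.21) and H2-Aa (1.06 ± 0.23) also rose. Ccl5 (-4.88 ± 0.68), the patrolling monocyte genes Cd300e (-3.23 ± 0.62) and Ace (-3.12 ± 0.63), and the granzyme Gzma (-4.14 ± 0.52) fell. Of the lipid- and scar-associated genes, 11 of 20 rose (14 adjusted over the list alone, camera adjusted p = 3.58e-11). Of the genes common to tissue macrophages, 8 of 16 rose (10 adjusted over the list alone, camera adjusted p = 1.41e-06 and adjusted p = 0.104 with an estimated correlation). Of the patrolling monocyte genes, 1 of 14 rose and 8 fell (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 2.85e-06 and adjusted p = 0.0584 with an estimated correlation). Shares stood apart by 0.79 (dissociation), 0.89 (hepatocyte), 0.05 (B and plasma cell), 0.03 (T and NK cell), 3.22 (stellate) and 0.36 (dendritic). The total of 596 was 351 without Sham6w replicate 1+2+5 and 396 without CBDL+DSS replicate 1. Libraries with single numbers gave 127 genes.

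Relative to advanced injury alone, the second hit came with higher Cd63 (from 33.6 ± 28.8 to 357 ± 27.5, log2 change 3.75 ± 0.50, adjusted p = 0.000156), Trem2 (from 5.03 ± 1.76 to 53.1 ± 3.89, log2 change 3.22 ± 0.44, adjusted p = 0.00018) and Apoe (from 413 ± 51.8 to 2449 ± 598, log2 change 2.54 ± 0.20, adjusted p = 4.68e-08), Mertk (2.22 ± 0.39) and the scavenger receptor Stab1 (2.54 ± 0.52) were higher too. Plac8 fell from 186 ± 54.0 to 33.5 ± 8.54 (log2 change -2.43 ± 0.27, adjusted p = 1.31e-05), as did the interferon-induced membrane protein Ifitm6 (-3.10 ± 0.30), S100a4 (-1.54 ± 0.29) and the lectin Clec10a (-1.89 ± 0.33). Among genes common to tissue macrophages, 10 of 16 rose (13 adjusted over the list alone, camera adjusted p = 3.23e-13). Of the lipid- and scar-associated genes, 10 of 20 rose (14 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.57e-09). Of the patrolling monocyte genes, 5 of 14 fell (7 adjusted over the list alone, camera adjusted p = 1.57e-06). Between these groups the shares stood apart by 2.68 (hepatocyte), 0.08 (T and NK cell), 0.43 (dendritic) and 5.59 (erythroid and platelet). In total 127 genes rose and 126 fell. The total of 253 was 168 or 135 without CBDL6w replicate 1 or 3, and 161 or 160 without CBDL+DSS replicate 2 or 3.

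In these macrophages the effect of colitis was more positive with ligation for Cd63 (log2 difference 4.82 ± 0.74, adjusted p = 0.00125), Apoe (log2 difference 3.95 ± 0.29, adjusted p = 1.59e-08), Mertk (3.73 ± 0.58), C1qa (2.73 ± 0.48), Fn1 (2.75 ± 0.52) and cathepsin D, Ctsd (2.40 ± 0.42). It was more negative for Plac8 (log2 difference -4.62 ± 0.40, adjusted p = 1.71e-07), Ms4a4c (-3.10 ± 0.54) and Ifitm6 (-2.55 ± 0.45). Of the genes common to tissue macrophages, 7 of 16 passed upward (11 adjusted over the list alone, camera adjusted p = 2.4e-12). Among the mitochondrial transcripts, 9 of 14 passed upward (14 adjusted over the list alone, camera adjusted p = 3.99e-20). Endothelial markers, at 0.241 to 0.277% of the reads in DSS and 0.00629 to 0.0614% in CBDL+DSS, moved with this contrast. In total 73 genes passed upward and 54 downward. The total of 127 was 75 or 74 without CBDL+DSS replicate 1 or 2.

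**Figure D2:**
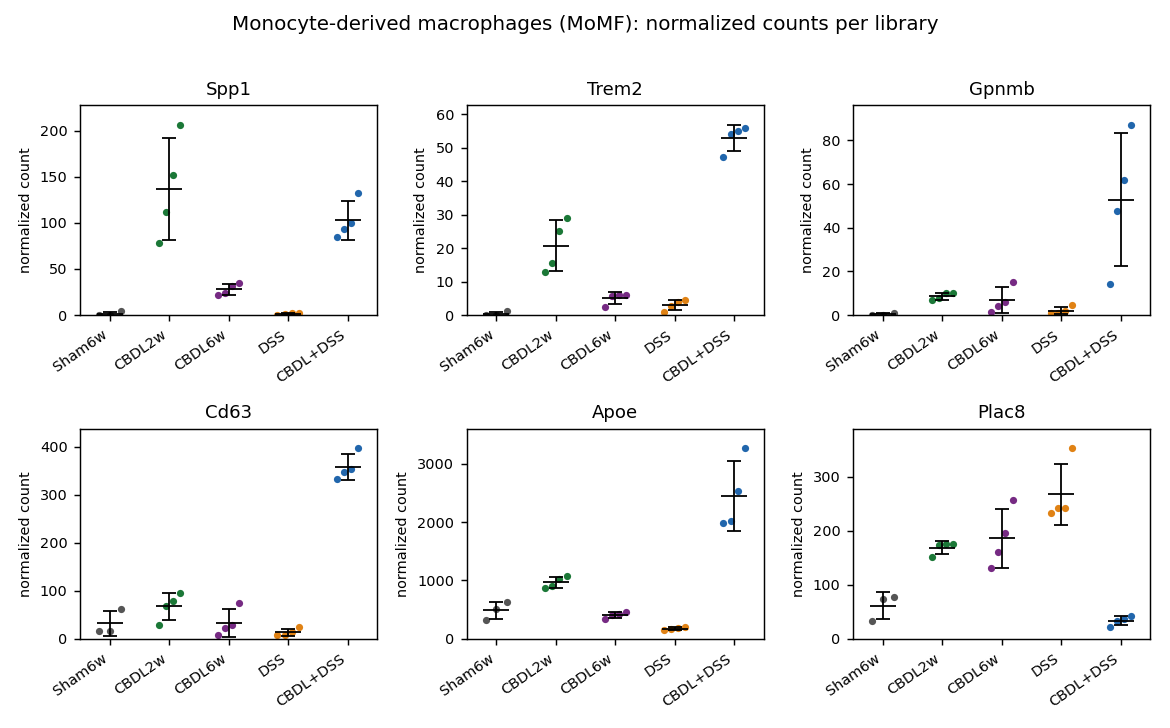
Normalized counts of Spp1, Trem2, Gpnmb, Cd63, Apoe and Plac8 in each library of monocyte-derived macrophages (points), by injury group, with the mean and SD of 4 libraries (3 for Sham6w). Spp1 averages 1.31 ± 2.27 in Sham6w and 103 ± 20.9 in CBDL+DSS, and Plac8 61.0 ± 25.0 in Sham6w and 267 ± 57 in DSS.

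Monocytes of the onset group were compared with 3 control libraries. The chitinase-like protein Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) rose from 35.1 ± 20.8 to 122 ± 8.46 normalized counts (log2 change 1.94 ± 0.39, adjusted p = 0.00147), the matrix proteoglycan Vcan from 27.6 ± 6.61 to 108 ± 30.9 (log2 change 1.91 ± 0.32, adjusted p = 0.000258), the acute-phase protein Saa3 from 8.56 ± 8.52 to 75.7 ± 37.7 (log2 change 3.34 ± 0.64, adjusted p = 0.00105) and Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) from 8.16 ± 5.40 to 45.7 ± 15.4 (log2 change 2.52 ± 0.46, adjusted p = 0.000578). Thrombospondin, Thbs1 (2.23 ± 0.37), the galectin Lgals3 (1.21 ± 0.18) and the integrin Itgam (1.07 ± 0.18) rose too. The fatty acid receptor Cd36 fell from 40.3 ± 8.06 to 4.25 ± 5.21 (log2 change -3.74 ± 0.77, adjusted p = 0.00188), and so did Bst2 (-2.78 ± 0.43) and Mrc1 (-3.59 ± 0.53). Bst2 is among the dendritic markers. Endothelial and dendritic shares fell as well, and whether these falls came from monocytes or from other cells was not tested. Of the genes of glycolysis and hypoxia, 12 of 20 rose (14 adjusted over the list alone, camera adjusted p = 2.57e-09), with the glycolytic enzyme Pgam1 at 1.72 ± 0.24. Of the classical monocyte genes, 8 of 17 rose (10 adjusted over the list alone, camera adjusted p = 6.06e-06), and of the patrolling monocyte genes 4 of 11 fell (5 adjusted over the list alone, camera adjusted p = 0.0014). Of the interferon-response genes, 6 of 23 fell (8 adjusted over the list alone, camera adjusted p = 0.000167 and adjusted p = 0.169 with an estimated correlation). Among ribosomal protein genes, 55 of 75 rose (65 adjusted over the list alone, camera adjusted p = 2.11e-35). All 15 endothelial genes fell (camera adjusted p = 3.1e-24), among them the phosphatase Ptprb (from 221 ± 83.3 to 5.56 ± 1.26, log2 change -5.04 ± 0.39, adjusted p = 6.77e-08) and the growth factor receptor Kdr (-5.28 ± 0.56). Siglech, a marker of plasmacytoid dendritic cells, fell (-5.04 ± 0.75), and marker shares stood apart by 0.72 (dissociation), 1.64 (ribosomal), 0.24 (hepatocyte), 0.07 (B and plasma cell), 0.1 (T and NK cell), 0.03 (endothelial), 0.14 (dendritic) and 0.43 (erythroid and platelet). In total 492 genes rose and 349 fell, or 341 and 501 without a filter on low values. The total of 841 was 547 without Sham6w replicate 3+6. Libraries with single numbers, which left 1 control, gave 176 genes.

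At the advanced stage monocytes rose in the glycolytic enzyme Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627) from 56.0 ± 24.4 to 128 ± 11.8 (log2 change 1.27 ± 0.24, adjusted p = 0.0011), in the cytokine Mif from 16.2 ± 5.41 to 44.7 ± 8.35 (log2 change 1.44 ± 0.31, adjusted p = 0.00336), in Plac8 (1.09 ± 0.26), Tgfbi (1.19 ± 0.23), Lgals3 (1.06 ± 0.18) and Ccr2 (0.81 ± 0.18). They fell in Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) from 157 ± 42.2 to 20.6 ± 12.1 (log2 change -3.02 ± 0.53, adjusted p = 0.000659), in the NF-kB inhibitor Tnfaip3 (-1.40 ± 0.26), the transcription factor Klf2 (-1.76 ± 0.31), Cd36 (-3.48 ± 0.77) and Bst2 (-2.37 ± 0.43). Of the glycolysis and hypoxia genes, 6 of 20 rose (13 adjusted over the list alone, camera adjusted p = 1.75e-07). Of the classical monocyte genes, 5 of 17 rose and 1 fell (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000817 and adjusted p = 0.0845 with an estimated correlation). Of the patrolling monocyte genes, 5 of 11 fell (6 adjusted over the list alone, camera adjusted p = 0.00101). Of the genes induced by dissociation, 8 of 22 fell (1 rose and 13 fell adjusted over the list alone, camera adjusted p = 2.51e-06 and adjusted p = 0.114 with an estimated correlation). Also 47 of 75 ribosomal protein genes rose (62 adjusted over the list alone, camera adjusted p = 2.33e-34). Again all 15 endothelial genes fell (camera adjusted p = 3.03e-26). Mrc1 went with them (157 in Sham6w, 128.5 in DSS, 17.3 to 34.8 with ligation), so its source stays open. Shares stood apart by 0.61 (dissociation), 1.59 (ribosomal), 0.38 (hepatocyte), 0.2 (B and plasma cell), 0.14 (T and NK cell), 0.04 (endothelial), 0.4 (stellate), 0.13 (dendritic) and 0.27 (erythroid and platelet). In total 359 genes rose and 326 fell, or 238 and 463 without a filter. The total of 685 was 388 without Sham6w replicate 3+6. Libraries with single numbers gave 97 genes.

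No gene passed between onset and advanced injury in monocytes (0 of 6112 in limma, 404 at an unadjusted p under 0.05, 0 in edgeR and 9 in DESeq2). Ccr2 stood at 404 ± 106 and 448 ± 91.2 at 2 and 6 weeks (log2 change -0.16 ± 0.17, adjusted p = 0.954). The count was 1 without CBDL2w replicate 1 or without CBDL6w replicate 3.

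Colitis alone changed 97 genes of monocytes, 64 up and 33 down. Spp1 fell from 25.2 ± 22.5 to 2.11 ± 3.54 (log2 change -3.35 ± 0.58, adjusted p = 0.0129), a call kept with each library left out. Plac8 rose from 211 ± 21.7 to 529 ± 104 (log2 change 1.3 ± 0.26, adjusted p = 0.0243), a call lost without Sham6w replicate 3+6 or DSS replicate 4. Cx3cr1 changed by -1.16 ± 0.24, a call lost without Sham6w replicate 1+2+5 or 3+6 or DSS replicate 4. Of the genes of oxidative phosphorylation, 5 of 40 rose (14 adjusted over the list alone, camera adjusted p = 2.04e-10). Of the patrolling monocyte genes, 2 of 11 fell (3 adjusted over the list alone, camera adjusted p = 0.00456). Endothelial markers held 0.286 to 0.629% of the reads, and other shares stood apart by 0.63 (mitochondrial), 1.35 (ribosomal), 0.33 (B and plasma cell) and 0.47 (erythroid and platelet). The total of 97 was 30 or 5 without Sham6w replicate 1+2+5 or 3+6 and 17 or 8 without DSS replicate 3 or 4, and libraries with single numbers gave 11.

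Against controls, monocytes of the second-hit group rose in Chil3 from 35.1 ± 20.8 to 245 ± 127 (log2 change 2.80 ± 0.39, adjusted p = 9.68e-05), Saa3 from 8.56 ± 8.52 to 97.5 ± 12.2 (log2 change 3.85 ± 0.64, adjusted p = 0.000457) and Thbs1 from 6.53 ± 1.81 to 47.5 ± 9.60 (log2 change 2.69 ± 0.37, adjusted p = 9.68e-05). Rises were also found in Vegfa (2.29 ± 0.46), Ldha (1.65 ± 0.24), Cd14 (1.43 ± 0.30) and the neutrophil collagenase Mmp8 (1.85 ± 0.36). The interferon regulator Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) fell from 47.8 ± 23.1 to 8.11 ± 3.77 (log2 change -2.39 ± 0.51, adjusted p = 0.00364), as did the ubiquitin-like Isg15 (-2.31 ± 0.40), Stat2 (-2.86 ± 0.60), Bst2 (-3.08 ± 0.43) and Ly6c2 (-0.97 ± 0.19). Of the interferon-response genes, 9 of 23 fell (13 adjusted over the list alone, camera adjusted p = 3.51e-08). Among glycolysis and hypoxia genes, 11 of 20 rose (16 adjusted over the list alone, camera adjusted p = 2.11e-10). Of the classical monocyte genes, 8 of 17 rose and 1 fell (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000185). Of the endothelial genes, 14 of 15 fell (15 adjusted over the list alone, camera adjusted p = 1.34e-19). The shares apart were 0.76 (mitochondrial), 1.51 (ribosomal), 0.52 (hepatocyte), 0.2 (B and plasma cell), 0.21 (T and NK cell), 0.07 (endothelial) and 0.15 (dendritic), with Bst2 among the dendritic markers. In total 428 genes rose and 371 fell, or 249 and 444 without a filter. The total of 799 was 502 or 414 without Sham6w replicate 1+2+5 or 3+6 and 512 without CBDL+DSS replicate 2, and libraries with single numbers gave 58.

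Relative to advanced injury alone, the neutrophil chemoattractant Cxcl1 rose from 13.4 ± 3.25 to 51.1 ± 6.82 (log2 change 1.88 ± 0.28, adjusted p = 0.00199) and cathepsin L, Ctsl, rose from 56.5 ± 8.07 to 136 ± 20.4 (log2 change 1.25 ± 0.18, adjusted p = 0.00199). Thoc7, a factor of messenger RNA export, fell from 148 ± 70.3 to 27.2 ± 7.67 (log2 change -2.34 ± 0.33, adjusted p = 0.00199). Of the inflammatory mediator genes, 3 of 21 rose (11 adjusted over the list alone, camera adjusted p = 3.12e-08 and adjusted p = 0.0946 with an estimated correlation), and of the genes induced by dissociation 4 of 22 rose (8 adjusted over the list alone, camera adjusted p = 3.49e-07 and adjusted p = 0.0946 with an estimated correlation). The shares apart were 1.4 (dissociation), 2.43 (neutrophil) and 3.27 (erythroid and platelet). In total 18 genes rose and 17 fell. The total of 35 was 22, 11, 20 or 20 without CBDL6w replicate 1, 2, 3 or 4 and 9, 7 or 6 without CBDL+DSS replicate 1, 2 or 6, and DESeq2 gave 93.

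For the difference in the effect of colitis with ligation, Plac8 passed in monocytes (log2 difference -2.27 ± 0.35, adjusted p = 0.0112). Of the oxidative phosphorylation genes, 1 of 40 passed downward (11 adjusted over the list alone, camera adjusted p = 1.76e-09). In total 7 genes passed upward and 12 downward. The total of 19 was 11 or 9 without CBDL+DSS replicate 1 or 6, 1 without CBDL6w replicate 1, 31 or 9 without DSS replicate 2 or 4, and 10 or 2 without Sham6w replicate 1+2+5 or 3+6.

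**Figure D3:**
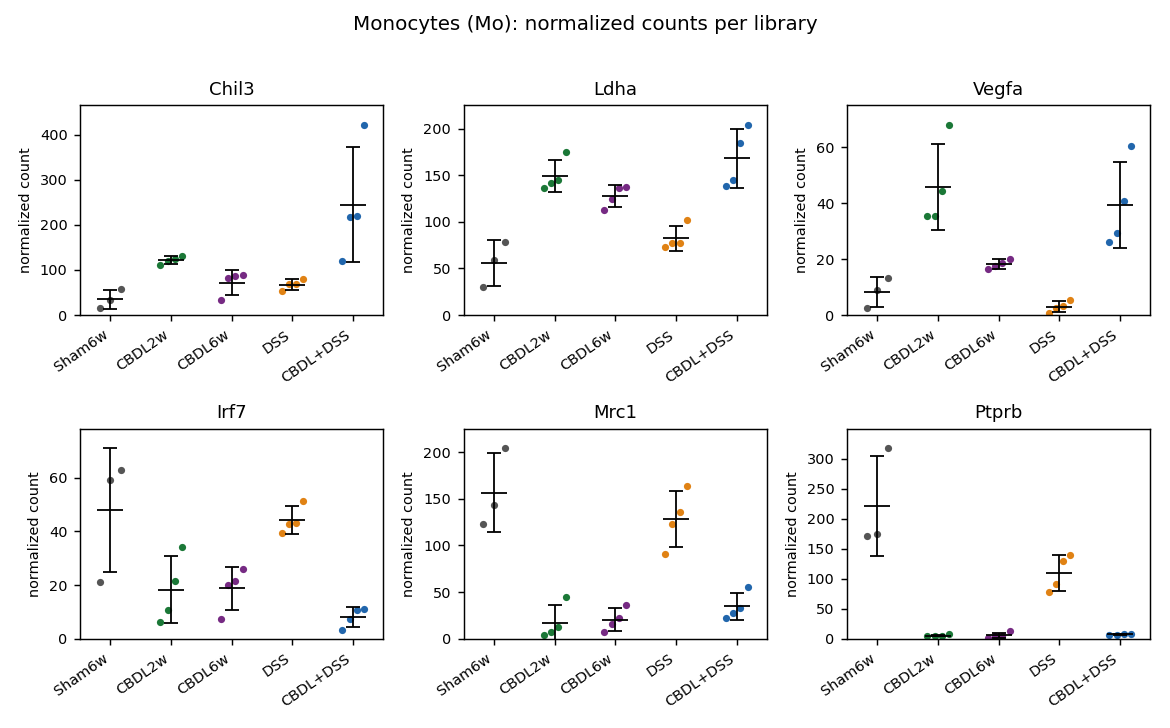
Normalized counts of Chil3, Ldha, Vegfa, Irf7, Mrc1 and Ptprb in each monocyte library (points), by injury group, with the mean and SD of 4 libraries (3 for Sham6w). Irf7 averages 47.8 ± 23.1 in Sham6w and 8.11 ± 3.77 in CBDL+DSS, and Mrc1 157 ± 42.2 in Sham6w and 20.6 ± 12.1 in CBDL6w.

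**Figure D4:**
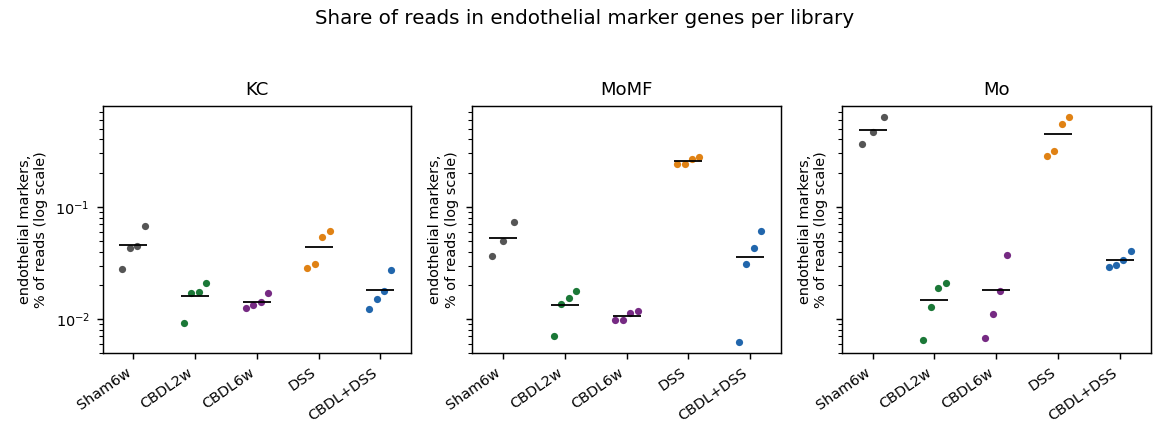
Percent of reads from the endothelial marker genes in each library (points, log scale), by injury group for each cell type, with a tick at the mean. Sham6w monocytes lie between 0.366 and 0.634%, and monocytes of the ligated groups between 0.00657 and 0.0405%.

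The cell types were also compared within each injury group. At CBDL2w Kupffer cells were above monocyte-derived macrophages in Clec4f (log2 difference 3.79 ± 0.66, adjusted p = 5.92e-05) and below them in Spp1 (log2 difference -2.69 ± 0.59, adjusted p = 0.00143) and S100a4 (-2.83 ± 0.33). They were above monocytes in the growth factor Igf1 (4.69 ± 0.47). Monocyte-derived macrophages exceeded monocytes in Apoe (log2 difference 2.60 ± 0.23, adjusted p = 2.32e-11), Mrc1 (2.57 ± 0.40), H2-Ab1 (2.17 ± 0.26) and Cd74 (2.14 ± 0.25). They fell below monocytes in Ly6c2 (-4.51 ± 0.47) and Vcan (-4.18 ± 0.54). Of the MHC class II genes, 7 of 12 were higher (10 adjusted over the list alone, camera adjusted p = 2.23e-22) in that pair. As for Kupffer cell genes, 19 of 21 were higher (20 adjusted over the list alone, camera adjusted p = 1.28e-35) in Kupffer cells than in monocyte-derived macrophages. The genes higher and lower numbered 289 and 212 between Kupffer cells and monocyte-derived macrophages, 601 and 485 between Kupffer cells and monocytes, and 93 and 59 between monocyte-derived macrophages and monocytes. The first total, 501, was 322 without MoMF replicate 4, and the third, 152, was 94 or 90 without MoMF replicate 1 or 2 and 57 without Mo replicate 4.

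At CBDL6w Kupffer cells exceeded monocyte-derived macrophages in Apoe (log2 difference 2.79 ± 0.23, adjusted p = 1.59e-12) and Cd63 (log2 difference 2.74 ± 0.50, adjusted p = 9.81e-05) and were lower in Plac8 (log2 difference -3.55 ± 0.39, adjusted p = 8.68e-09). They exceeded monocytes in the folate receptor Folr2 (4.79 ± 0.65) and in Slc40a1 (4.60 ± 0.56). For Kupffer cell genes, 16 of 21 were higher (19 adjusted over the list alone, camera adjusted p = 1.06e-17) in the first pair. Monocyte-derived macrophages exceeded monocytes in Clec10a (2.89 ± 0.52) and H2-Eb1 (1.96 ± 0.29). Of the patrolling monocyte genes, 8 of 14 were higher (11 adjusted over the list alone, camera adjusted p = 6.13e-12). The genes higher and lower numbered 403 and 327, 611 and 542, and 98 and 65 for the same 3 pairs. The third total, 163, was 96 without MoMF replicate 3 and 100 or 91 without Mo replicate 1 or 4.

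In DSS Kupffer cells exceeded monocyte-derived macrophages in Cd163 (log2 difference 5.09 ± 0.58, adjusted p = 5.24e-09), Clec4f (4.16 ± 0.66) and the phosphatidylserine receptor Timd4 (log2 difference 4.30 ± 0.59, adjusted p = 3.16e-07). They were lower in the endothelial genes Kdr (log2 difference -3.13 ± 0.60, adjusted p = 0.000125) and Igfbp7 (-3.26 ± 0.45). Among Kupffer cell genes, 16 of 21 were higher and 1 were lower (18 were higher and 1 were lower adjusted over the list alone, camera adjusted p = 8.71e-20). Of the endothelial genes, 12 of 15 were lower (13 adjusted over the list alone, camera adjusted p = 2.14e-12). Monocyte-derived macrophages were below monocytes in Fn1 (log2 difference -5.60 ± 0.46, adjusted p = 8.44e-13), Saa3 (-4.59 ± 0.64) and Ly6c2 (-4.22 ± 0.47), while of the patrolling monocyte genes 8 of 14 were higher (10 adjusted over the list alone, camera adjusted p = 9.37e-15). The genes higher and lower numbered 475 and 544, 469 and 639, and 96 and 79. The third total, 175, was 112 without Mo replicate 2.

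In CBDL+DSS Kupffer cells exceeded monocyte-derived macrophages in the scavenger receptor Marco (log2 difference 3.62 ± 0.64, adjusted p = 8.33e-05) and in Cd5l (log2 difference 3.69 ± 0.50, adjusted p = 7.4e-07), a secreted protein of macrophages. They were lower in Spp1 (log2 difference -3.23 ± 0.59, adjusted p = 0.000153), the coagulation factor F13a1 (-3.38 ± 0.53) and Ccr2 (-2.73 ± 0.23). Monocyte-derived macrophages exceeded monocytes in the chemokine Cxcl16 (2.84 ± 0.39), Cd63 (log2 difference 2.80 ± 0.50, adjusted p = 0.000144), the efferocytosis receptor Axl (2.63 ± 0.38) and Apoe (2.57 ± 0.23), and were lower in Vcan (-4.86 ± 0.54) and Chil3 (-4.17 ± 0.66). Of the Kupffer cell genes, 19 of 21 were higher (19 adjusted over the list alone, camera adjusted p = 1.29e-32) in Kupffer cells than in monocyte-derived macrophages. Between monocyte-derived macrophages and monocytes, of the genes of glycolysis and hypoxia 9 of 20 were lower (9 adjusted over the list alone, camera adjusted p = 7.23e-12). The genes higher and lower numbered 205 and 164, 587 and 503, and 147 and 177. The first total, 369, was 236 without KC replicate 2, and the third, 324, was 187 without Mo replicate 4+5.

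Whether an injury changed genes differently between cell types was tested as the difference of the effects against Sham6w. The effect of CBDL6w was more positive in Kupffer cells than in monocyte-derived macrophages for Cd63 (log2 difference 3.52 ± 0.74, adjusted p = 0.0127) and Cx3cr1 (log2 difference 2.78 ± 0.45, adjusted p = 0.000922). It was also more positive in Kupffer cells than in monocytes for Cx3cr1 (3.29 ± 0.45), Cd63 (3.83 ± 0.74) and Fn1 (3.15 ± 0.68). Endothelial genes differed between Kupffer cells and monocytes, where 7 of 15 passed upward (14 adjusted over the list alone, camera adjusted p = 6.27e-19). The effect was more positive in one cell type than the next for 18 genes and more negative for 12 between Kupffer cells and monocyte-derived macrophages (13 and 2 with edgeR), 96 and 23 between Kupffer cells and monocytes, and 41 and 8 between monocyte-derived macrophages and monocytes (2 and 0 with edgeR). The median of all genes was 0.162 in the last, and 0.04 with edgeR. Leaving out 1 library moved the first total of 30 to 15 or 56 (KC CBDL6w replicate 1 or 3) and to 12, 153 or 151 (MoMF Sham6w replicate 1+2+5, 3 or 4+6). The balance turned over to 27 and 29 without KC CBDL6w replicate 3, and to 35 and 118 and 38 and 113 without the last 2 libraries. It moved the second total of 119 to 77 (KC CBDL6w replicate 2), 71 or 75 (KC Sham6w replicate 1 or 2), 79 or 76 (Mo CBDL6w replicate 1 or 2) and 48 (Mo Sham6w replicate 3+6). The third total of 49 became 10, 91 or 91 (MoMF Sham6w replicate 1+2+5, 3 or 4+6), 10 or 32 (Mo CBDL6w replicate 1 or 3) and 26, 11 or 27 (Mo Sham6w replicate 1+2+5, 3+6 or 4).

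For DSS the effect was more positive in Kupffer cells than in monocyte-derived macrophages for the chromatin protein Hmgb2 (log2 difference 2.46 ± 0.48, adjusted p = 0.00359), and more negative for Ctsl (log2 difference -2.31 ± 0.37, adjusted p = 0.000302) and lysozyme, Lyz1 (-2.30 ± 0.37). Apoe had a more negative effect in Kupffer cells than in monocytes (log2 difference -1.96 ± 0.35, adjusted p = 0.00242). Endothelial genes differed between the first pair, where 3 of 15 passed downward (10 adjusted over the list alone, camera adjusted p = 4.15e-09). The genes with more positive and more negative effects numbered 14 and 51 for Kupffer cells against monocyte-derived macrophages (10 and 17 with edgeR), 6 and 12 against monocytes (2 and 11 with edgeR, 35 and 20 without a filter), and 3 and 0 for monocyte-derived macrophages against monocytes (limma, 1 in all with edgeR). The first total of 65 became 34 or 39 (KC DSS replicate 1 or 2), 20 (MoMF DSS replicate 5+6) and 39, 145 or 127 (MoMF Sham6w replicate 1+2+5, 3 or 4+6). The second total of 18 became 11 without KC DSS replicate 2 or Mo Sham6w replicate 1+2+5. The third total of 3 became 6, 0 or 0 (MoMF DSS replicate 2, 3 or 5+6), 11, 30 or 16 (MoMF Sham6w replicate 1+2+5, 3 or 4+6), 0, 0 or 1 (Mo DSS replicate 2, 3 or 4) and 0 (Mo Sham6w replicate 3+6).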

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

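The tests of other explanations and of other splits below were chosen after the result was seen, except the correlation of endothelial genes; the tests of differences between effects were set before. The search covered 139 groups of 4 libraries for library measures, where 8 libraries stood apart, and 111 for marker genes, where 4 did. By design chance flags about 1 in 20 groups; unrounded shares and a minimum group mean of 0.01% were set after a first look.

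Among Kupffer cells, CBDL2w replicate 4 had a read total of 452668 (the others 339462 to 345365), CBDL6w replicate 4 a ribosomal protein share of 12.3801% (10.22 to 10.509%) and CBDL6w replicate 1 a hepatocyte share of 0.12285% (0.018 to 0.028%). Kupffer cell DSS replicate 4 had a hepatocyte share of 0.3152% (0.031 to 0.059%) and DSS replicate 1 a Clec4f level of 211.0 (177.62 to 182.569). In monocyte-derived macrophages, CBDL6w replicate 2 had a ribosomal protein share of 10.48661% (14.704 to 15.5%) and a Cd74 level of 389 (643.474 to 672.997), and DSS replicate 1 a B and plasma cell share of 0.07707% (0.021 to 0.03%). In monocytes, CBDL2w replicate 2 had a dissociation gene share of 0.99526% (1.171 to 1.182%) and a Cd5l level of 124.4 (21.55 to 31.704), CBDL+DSS replicate 1 a ribosomal protein share of 13.12828% (15.015 to 15.119%) and CBDL+DSS replicate 6 a Ccr2 level of 338.9 (368.598 to 371.365).

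Endothelial genes were lower in monocytes of the 3 ligated groups than in Sham6w, with Ptprb at 5.56 ± 1.26 and Kdr at 3.50 ± 2.19 normalized counts at CBDL2w against 221 ± 83.3 and 162 ± 38.4. An even share of RNA of liver cells of every kind in the control libraries is argued against, since the hepatocyte share was 2.62 times as high in Sham6w as in CBDL6w and the endothelial share 26.68 times, with the widest hepatocyte ratio between libraries (5.00) under the narrowest endothelial one (9.83). Markers of dendritic (7.75 times), T and NK (7.07), B and plasma (5.08) and erythroid cells (3.70) were higher in Sham6w too, in each library, so an uneven mix of cells stays open. None of the 15 tested endothelial genes is in another list. Across them, levels in Sham6w monocytes and DSS monocyte-derived macrophages had Pearson r = 0.94 and Spearman rho = 0.85. With genes not independent and no other groups correlated, r cannot decide whether endothelial RNA in control libraries accounts for the pattern. A sort that removes CD31-positive cells would test it (no gate is given). An effect of ligation on endothelial cells or on their contact with monocytes stays open and untested.

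Ribosomal protein genes were higher in Kupffer cells of the injury groups than in Sham6w, a call that held with an estimated correlation in all but CBDL+DSS; mitochondrial transcripts, lower but with shares that overlapped (at least 6.45% in Sham6w against at most 7.23%), were not weighed. A difference in depth is argued against, since the median Sham6w total was 1.05 times that of the 16 injury libraries, 3 of 4 Sham6w totals lay within their range of 228741 to 512401, and the ribosomal share lay wholly below (at most 8.34% against at least 8.93%). The deposited scaling is argued against as the whole cause, as the median change of the ribosomal protein list in DSS at equal totals was 0.604. A preparation of the Sham6w mice apart from the others cannot be told apart from an effect of injury, because each injury comparison shares the Sham6w libraries and no label gives a batch; the median between CBDL+DSS and CBDL6w was -0.103.

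Cx3cr1, Cd63, Ccr2 and Fn1 were higher and Clec4f lower in Kupffer cells at CBDL2w and CBDL6w. The tests were recast after values were seen: a first form set the first quartile of the implied MoMF or Mo share over 35 genes that rose (49.8%) against the third over 13 MoMF genes (17.7%). A second counted 6 genes higher in Kupffer cells than in both others. Admixture is argued against for Cx3cr1 and Cd63, which would need at least 86.2% of such cells in the lowest CBDL6w library (251.1 and 97.8 counts, against at most 286.5 and 74.9 in a MoMF or Mo library), while genes high in MoMF over Kupffer cells implied -0.01 to 37.56%. It is also argued against for Clec4f, which fell by 60.6% in the CBDL6w library with the smallest fall, past the 17.7%. Admixture may account for Ccr2 (23.7%) and Fn1 (12.9%), and a change within Kupffer cells, or their replacement by other cells in the same gate, stays open and untested.

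The difference in the effect of colitis with ligation passed for 371 genes in Kupffer cells, 127 in monocyte-derived macrophages and 19 in monocytes. A change common to all injuries also enters it. As large a count came in 1, 2 and 1 of 100 drawn splits (highest other 73, 158 and 1). Splits above the real count may reflect sample structure, which was not tested. Between cell types the effect of CBDL6w differed for 30, 119 and 49 genes (Kupffer cells against monocyte-derived macrophages, then each against monocytes). As many came in 8, 7 and 9 of 100 splits (highest other 481, 320 and 592). For the effect of DSS the counts were 65, 18 and 3, with as many in 2, 2 and 30 of 100 splits (highest other 378, 69 and 198). These splits also break up the effects themselves, or leave that of 1 cell type in place, as the highest other split did in 5 of the last 6. Their counts may thus hold an injury effect, and they decide nothing about chance for a difference between effects.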

How the results depend on the processing

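The endothelial covariate was added, and its test chosen, only after the data were seen; the other alternatives were fixed before. Counts of genes are given where they moved by over 1.5 times, with KC for Kupffer cells, MoMF for monocyte-derived macrophages and Mo for monocytes, and the cause was not tested unless named. Of the called values of named genes, the direction was kept in every alternative listed here except 1 with libraries of single numbers (Tlr13, Sham6w MoMF against Mo, -0.038) and 52 with the covariate. Calls were lost in 61 of 2029 with a pseudocount of 5, 350 of 2029 without a filter (more genes tested), 19 of 735 at equal totals, 196 of 2029 in edgeR, 12 of 734 in DESeq2 and 647 of 1924 with libraries of single numbers (fewer libraries). Leaving out 1 library lost 3081 of 16786, and 159 of 1651 list calls. Of 219 list calls in the 18 injury comparisons, 51 held with an estimated correlation and 168 did not (227 of 578 held over all 42 comparisons). Of the 219, 2 were lost with a pseudocount of 5, 6 at equal totals and 21 with libraries of single numbers, where 4 also reversed in MoMF: oxidative phosphorylation at CBDL2w (-0.032) and CBDL6w (-0.009), and ribosomal protein genes in DSS (-0.166) and CBDL+DSS (-0.102).

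Without a filter on low values, where more genes were tested, KC gave 128 genes for CBDL6w, 241 for DSS, 133 for CBDL+DSS, 33 for CBDL+DSS against CBDL6w and 170 for colitis by ligation. MoMF gave 3 for CBDL2w against CBDL6w, 155 for CBDL+DSS against CBDL6w and 83 for colitis by ligation, and Mo gave 26 for DSS, 13 for CBDL+DSS against CBDL6w and 3 for colitis by ligation. MoMF against Mo in Sham6w gave 800, and the effects gave 112 (CBDL6w, MoMF against Mo), 55 (DSS, KC against Mo) and 49 (DSS, MoMF against Mo). DESeq2 gave 309, 330, 10 and 231 in KC (CBDL2w, CBDL+DSS, CBDL2w against CBDL6w, CBDL+DSS against CBDL6w), 295, 137, 205, 31 and 462 in MoMF (CBDL2w, CBDL6w, DSS, CBDL2w against CBDL6w, CBDL+DSS against CBDL6w), and 261, 9 and 93 in Mo (DSS, CBDL2w against CBDL6w, CBDL+DSS against CBDL6w). A pseudocount of 5 gave 217, 11 and 194 in MoMF (DSS, CBDL2w against CBDL6w, colitis by ligation), 191 and 131 for the CBDL6w effect (KC against Mo, MoMF against Mo) and 105 and 58 for the DSS effect (KC against MoMF, MoMF against Mo). With edgeR there were 52 genes for Mo DSS, 241 for Sham6w MoMF against Mo, 15, 51 and 2 for the CBDL6w effect (KC against MoMF, KC against Mo, MoMF against Mo) and 27 and 1 for the DSS effect (KC against MoMF, MoMF against Mo). Equal totals gave 2 for MoMF CBDL2w against CBDL6w.

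Libraries with single numbers, fewer in each fit, gave 82, 20 and 220 in KC (CBDL+DSS, CBDL+DSS against CBDL6w, colitis by ligation), 53, 17, 22, 127 and 10 in MoMF (CBDL2w, CBDL6w, DSS, CBDL+DSS, CBDL2w against CBDL6w) and 176, 97, 11, 58 and 8 in Mo (CBDL2w, CBDL6w, DSS, CBDL+DSS, colitis by ligation). The Sham6w controls of MoMF and Mo then held 1 library each, assumed to vary like the other groups. Between cell types they gave 328, 509 and 7 in Sham6w and 183, 634 and 181 in CBDL+DSS (KC against MoMF, KC against Mo, MoMF against Mo).

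With the replicate number as a replicate block there were 92 and 12 genes in KC (CBDL+DSS, CBDL+DSS against CBDL6w), 55 in MoMF DSS, and 42, 444 and 6 in Mo (DSS, CBDL+DSS, CBDL+DSS against CBDL6w). Of the named-gene calls 175 of 1842 were lost, and 10 list calls. In no comparison did every pair of libraries with the same number correlate above 0.1, the limit set for a pairing, so they were read as numbers only, although between cell types the mean over same-number pairs (0.017 to 0.055) lay above that of other pairs (-0.018 to -0.006). With injury group and number as a random block between cell types, which the labels do not tie to an animal, the consensus correlation was 0.0375.

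The groups held 91.6% of the variance of the endothelial covariate in MoMF and 95.8% in Mo, so there this fit cannot part the 2, and 70.4% in KC, where it parts them in part. It gave 26, 19, 412 and 59 genes in KC (CBDL2w, CBDL6w, DSS, CBDL+DSS), 11, 0, 0, 81 and 34 in MoMF (CBDL2w, CBDL6w, DSS, CBDL+DSS against CBDL6w, colitis by ligation) and 0, 0, 54, 0, 13 and 3 in Mo (CBDL2w, CBDL6w, DSS, CBDL+DSS, CBDL+DSS against CBDL6w, colitis by ligation). Of 836 called named-gene values 492 lost their call and 52 changed sign, and of 219 list calls 58 were lost and 16 changed sign.

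Leaving out 1 library at a time gave these ranges (libraries with joined numbers in brackets where they widen the range or moved a count by over 1.5 times). KC: CBDL2w 85 to 156, CBDL6w 99 to 259, DSS 214 to 394, CBDL+DSS 108 to 166 (132 without 4+5), CBDL2w against CBDL6w 0 to 1 (limma), CBDL+DSS against CBDL6w 28 to 108 (68 and 50 without 1+3 and 4+5), colitis by ligation 191 to 431. MoMF: CBDL2w 114 to 440, CBDL6w 49 to 205 (120 without Sham6w 4+6), DSS 37 to 289 (53 without DSS 5+6), CBDL+DSS 396 to 849 (351 without Sham6w 1+2+5), CBDL2w against CBDL6w 1 to 10, CBDL+DSS against CBDL6w 135 to 340, colitis by ligation 74 to 173 (190 without Sham6w 1+2+5). The median of the ribosomal protein list in MoMF CBDL2w against CBDL6w ran from -0.062 (without CBDL6w replicate 2) to 0.191. Mo without Sham6w 3+6: 547 (CBDL2w), 388 (CBDL6w), 5 (DSS), 414 (CBDL+DSS) and 2 (colitis by ligation), and without Sham6w 1+2+5: 30 (DSS), 502 (CBDL+DSS) and 10 (colitis by ligation). Other Mo ranges: DSS 8 to 134, CBDL+DSS 512 to 766, CBDL2w against CBDL6w 0 to 1, CBDL+DSS against CBDL6w 6 to 22 (28 without CBDL+DSS 4+5), colitis by ligation 1 to 31. Between cell types: Sham6w KC against MoMF 676 (without MoMF 1+2+5), MoMF against Mo 269 and 289 (without Mo 1+2+5 and 3+6), CBDL2w KC against MoMF 322 to 479 and MoMF against Mo 57 to 146, CBDL6w MoMF against Mo 91 to 159, DSS MoMF against Mo 112 to 153, CBDL+DSS KC against MoMF 236 to 301 (305 without MoMF 4+5) and MoMF against Mo 187 (without Mo 4+5). CBDL6w effect: KC against MoMF 15 to 153 (12 and 151 without MoMF Sham6w 1+2+5 and 4+6), KC against Mo 71 to 113 (48 without Mo Sham6w 3+6), MoMF against Mo 10 to 91 (10 and 91 without MoMF Sham6w 1+2+5 and 4+6, 26 and 11 without Mo Sham6w 1+2+5 and 3+6). DSS effect: KC against MoMF 34 to 145 (39 and 127 without MoMF Sham6w 1+2+5 and 4+6, 20 without MoMF DSS 5+6), KC against Mo 11 to 27 (11 without Mo Sham6w 1+2+5), MoMF against Mo 0 to 30 (11 and 16 without MoMF Sham6w 1+2+5 and 4+6, 0 without MoMF DSS 5+6 or Mo Sham6w 3+6).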

Other observations

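In Kupffer cells the effect of colitis was more positive with ligation for scavenging and phagocytosis receptors, of which 5 of 19 passed upward and 1 passed downward (9 passed upward and 1 passed downward adjusted over the list alone, camera adjusted p = 8.76e-05). It was also more positive for heme and iron genes, of which 5 of 15 passed upward (6 adjusted over the list alone, camera adjusted p = 0.00283), with Hmox1, the heme-degrading enzyme, at 1.41 ± 0.35.

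The tests of other splits were chosen after the results were seen. All splits into groups of the same sizes were counted, 35 per comparison unless said. In each but 3, 1 of 35, the real split, gave as many genes. That share is the smallest possible, unadjusted over comparisons, so chance is not excluded. The real count and the highest of the other splits in Kupffer cells were 167 and 1 (CBDL2w), 200 and 4 (CBDL6w), 486 and 2 (DSS), 204 and 0 (CBDL+DSS, limma) and 107 and 2 (CBDL+DSS against CBDL6w). In monocyte-derived macrophages they were 186 and 2, 74 and 68, 126 and 18, 596 and 56, and 253 and 3 in the same order, and 5 and 0 for CBDL2w against CBDL6w. In monocytes they were 841 and 611, 685 and 129, 97 and 2, 799 and 177, and 35 and 2. For CBDL2w against CBDL6w in Kupffer cells and in monocytes 0 genes passed in limma. Then 35 of 35 splits gave as many (highest other 1 in each), which says nothing about chance. Between cell types (Kupffer cells against monocyte-derived macrophages, then each against monocytes) they were 501 and 1, 1086 and 88, and 152 and 10 in CBDL2w. In CBDL6w they were 730 and 346, 1153 and 138, and 163 and 19, in DSS 1019 and 50, 1108 and 123, and 175 and 8, and in CBDL+DSS 369 and 3, 1090 and 37, and 324 and 5. In Sham6w they were 1204 and 474, and 1210 and 590, and for monocyte-derived macrophages against monocytes 465 and 85, where 10 splits are too few for a share under 0.05.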
